A study of Tetrahymena thermophila with 11 samples.

How the data were processed

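Small RNA of vegetatively growing Tetrahymena thermophila was sequenced in 11 libraries. Per the labels, 5 libraries hold total small RNA, from the wild-type strains CU522 and SB210 and from knockouts of Rdf1, Rdf2 and Rdn2, and 6 hold RNA bound to tagged Twi2, Twi7, Twi8, Twi9, Twi10 or Twi12. Each group has 1 library, so no test between groups and no p-value was possible. The knockouts were compared with SB210 and the immunoprecipitates with the CU522 total library, the strains the labels give. The labels say that cells for immunoprecipitation were grown with cadmium chloride to induce the tagged protein; whether the CU522 total library was grown with it is not given in the sources used here.

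The deposited files give, for each library, 1 list of sequences that the authors mapped to the genome and 1 list of those they did not map, 22 files in all. Values in both lists are counts, the number of reads of each distinct sequence, per the file headers and as the authors deposited them, with no normalization. The mapped lists also give counts of reads made of the mapped sequence plus 1 further 3' base (A, C, G or T), and the number of genome positions matched. No such extended read was listed elsewhere in its library, so these were read as reads whose last base kept them from mapping as a whole, and they were added to the mapped reads as sequences of their own with that base attached. The trimming, the aligner, its mismatch limit and the genome build are not given in the sources used here. No genome coordinates were in the files and no genome sequence was used, so positions, loci, phasing and sense or antisense to genes were not analysed here. The table of protein-coding genes at hand was not used, because no sequence could be placed on it. Reads from the disrupted genes themselves were not analysed here, because the gene sequences were not used.

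All 22 files were sorted by sequence and stopped at TTACAA, so that no sequence starting with TTAG or a later word was listed. Shares of sequences starting with T are therefore lower bounds, and all totals refer to the listed reads. In the mapped list of the Twi12 immunoprecipitate, the 5 count columns are named for Twi10, hold the Twi10 value for the 2588 sequences shared with the Twi10 list and 0 for the other 606395. These columns were not used, and for that list only the distinct sequences and their lengths and numbers of positions were described. Its non-mapped counts are named for Twi12 and were used.

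Reads were grouped by length into under 18, 18 to 22, 23 to 24, 25 to 27, 28 to 30, and 31 nt and over. Shares carry Wilson 95% binomial intervals, and ratios carry 95% intervals from the counts. PCR reads without molecular identifiers are not independent molecules, so these intervals and the floor of 3 counts cover counting error only, and not the difference between cultures or libraries. Numbers of distinct sequences were compared at an equal depth of 100000 mapped reads by the expected number in a random draw.

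RPM below means reads in every 1000000 reads of the named total. Changes were called on distinct mapped sequences of 23 to 24 nt, scaled to the mapped reads of the library. A sequence was tested with at least 50 reads over the pair of libraries and called changed at a fold of at least 4, with counts of 0 raised to the floor of 3 counts. This minimum favours sequences abundant in the deeper library of a pair, so the balance of higher and lower calls can follow depth. As the design set out for files without positions, sequences took the place of loci. The rule for named sequences took the 5 with the most reads of 23 to 24 nt in each library, the 3 most abundant mapped sequences of any size, the 5 largest folds up for each immunoprecipitate, and the 5 largest folds up and down for each knockout. In the knockouts a named fold had to be at least 1.5 times larger than that of CU522 against SB210 in the same direction. The text gives examples of these, and says where a sequence was chosen otherwise. The thresholds for calling a change, the size classes, the comparisons with the controls and the naming rule were fixed before the data were examined. The tRNA pattern below was not part of that design, which named tRNA by labels or annotation.

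Other measures were made on the sequences alone. Telomeric reads had at least 12 consecutive bases of the GGGGTT repeat or of its complement, with shuffled repeats of the same bases as the control, and were scaled to all listed reads of the library. Reads with the tRNA pattern matched TRGYNNANNNG, the A-box of tRNA genes (R is A or G, Y is C or T, N is any base), starting at base 8, where it lies in a 5' tRNA fragment, with starts at bases 6, 7, 9 and 10 as the background. The pattern is a short motif and can match other RNAs, so shares are also given without 1 abundant family at 1 genome position. Non-mapped reads were matched to mapped sequences after removal of 1 to 3 bases from the 3' end, with removal from the 5' end as the background. Overlaps between strands of distinct 23 to 24 nt sequences that matched 1 genome position and were listed without an extra 3' base were counted at 16 to 24 bases, with reversed sequences as the background. Libraries were compared by Spearman's rank correlation over sequences with at least 50 reads in all. The sequences changed in each knockout were looked up in the immunoprecipitates and set against 10000 random lists matched on abundance in 10 bins. Overlaps between knockouts, which share the SB210 library, were compared with 20 simulations of unchanged sequences.

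The calling rule was tested on simulated data in which 200 sequences were changed by known folds, all well beyond the 4-fold rule, with counting error only. It recovered 200 in the CU522 and SB210 pair, 191 for the Rdf1 knockout, 200 for the Rdf2 knockout and 200 for the Rdn2 knockout. Of the unchanged sequences it called 2 of 4645, 0 of 1470, 1 of 4050 and 5 of 5202 in these pairs. The simulations held no difference between cultures or libraries. They therefore check the working of the rule and not its error rate in real pairs. Alternatives changed the size window, the counting of distinct sequences in place of reads, the control library, the scaling, the minimum number of reads, the floor and the sequences admitted. The work used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.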

Results

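Small RNA from vegetatively growing cells of the ciliate Tetrahymena thermophila was sequenced in 11 libraries, with 1 library per group and no replicates. The total small RNA libraries came from the wild-type strains CU522 and SB210 and from SB210-derived knockouts of Rdf1, Rdf2 and Rdn2. Rdf1, Rdf2 and the nucleotidyltransferase Rdn2 are partners of the RNA-dependent RNA polymerase Rdr1, whose product is cut by Dicer. The other 6 libraries hold RNA bound to 1 tagged Piwi protein each, namely Twi2, Twi7, Twi8, Twi9, Twi10 and Twi12, in the CU522 background. The study's title asks for the sequence, the biogenesis and the function of the small RNA classes these proteins bind. The listed mapped reads numbered 1734910 in CU522, 411355 in SB210, 211744 in the Rdf1 knockout, 1397801 in the Rdf2 knockout and 2028438 in the Rdn2 knockout. They numbered 1461790 for Twi2, 3026091 for Twi7, 1951314 for Twi8, 367450 for Twi9 and 1205720 for Twi10. For Twi12 no mapped read count was usable, and 608983 distinct mapped sequences and 1518314 non-mapped reads were described. Mapped reads were 32.7% of all listed reads in the Rdf1 knockout, the lowest share, and 76.5% for Twi7, the highest. Intervals are 95% intervals for counting error only.

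RNA of 23 to 24 nt made up most mapped reads in both wild types and in all 3 knockouts. Its share was 90.4% in CU522 (Wilson interval 90.3 to 90.4), 90.8% in SB210 (90.7 to 90.9), 94.2% in the Rdn2 knockout, 88.1% in the Rdf2 knockout and 74.9% in the Rdf1 knockout (74.7 to 75.1). Without Rdf1 the RNA was shorter, since 24.6% of mapped reads had 18 to 22 nt against 8.97% in SB210. The ratio of the 23 to 24 nt share to that of SB210 was 0.825 for the Rdf1 knockout (0.822 to 0.827), 0.970 for the Rdf2 knockout and 1.04 for the Rdn2 knockout. It remained the main class in each of the 3 knockouts. These shares are relative to each library's total, so they do not measure the amount of RNA per cell.

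The Twi libraries differed in the size of the RNA they held. Among mapped reads, Twi2, Twi7 and Twi10 held mainly 23 to 24 nt RNA, at 94.2%, 88.0% and 85.4%. Of all listed Twi10 reads only 41.5% were mapped. Its non-mapped reads had 24.1% at 23 to 24 nt and 67.1% at 31 nt and over, while those of Twi2 and Twi7 had 90.8% and 80.8% at 23 to 24 nt. Twi8 held 67.5% of its reads in that class and 32.3% at 18 to 22 nt. Twi9 held only 11.3% there (11.2 to 11.4), with 18.7% at 18 to 22 nt, 22.6% at 25 to 27 nt, 38.3% at 28 to 30 nt and 9.10% at 31 nt and over. Among the distinct mapped sequences of Twi12, 0.746% had 23 to 24 nt, 40.0% had 18 to 22 nt and 21.3% had 28 to 30 nt. Against CU522 the share of 23 to 24 nt fell to a ratio of 0.747 for Twi8, 0.125 for Twi9 and 0.945 for Twi10. For Twi2 and Twi7 the log2 ratios were 0.06 and -0.04, and both changed sign when distinct sequences were counted in place of reads, so no direction is given. CU522 had 10 mapped reads of 28 to 30 nt and 2 of 31 nt and over, and SB210 had 0 of each. Whether all libraries were cut to the same size range was not examined here. Size differences between libraries therefore need not be traits of the proteins alone.

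**Figure D1:**
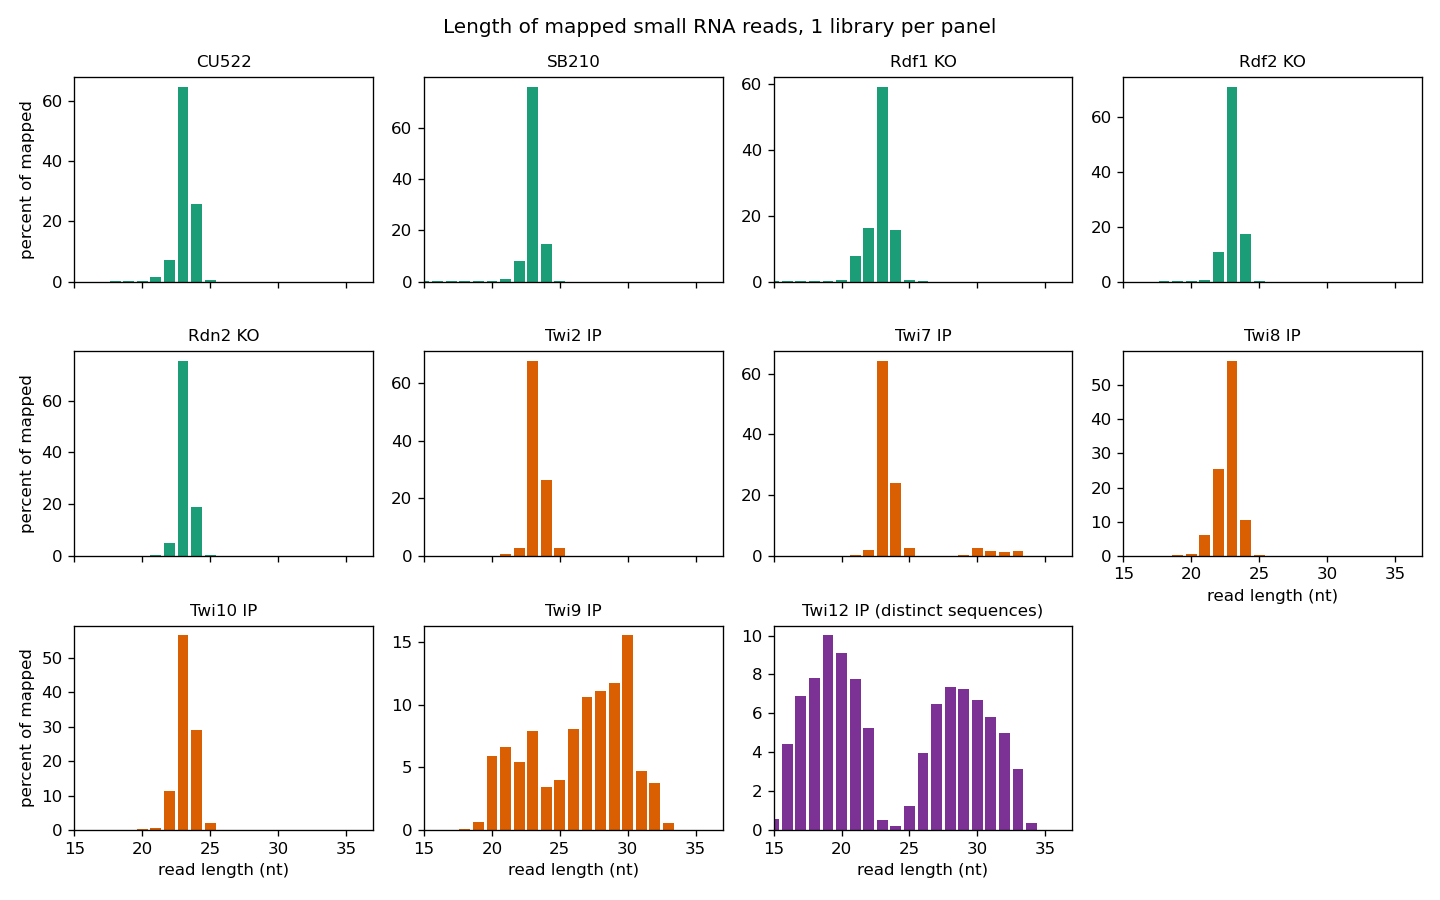
Length of mapped reads in nt (x axis) against percent of mapped reads (y axis, with its own scale in each panel), 1 library per panel; green panels are total small RNA, orange panels are immunoprecipitates, and the purple Twi12 panel shows percent of distinct sequences. The 23 to 24 nt class holds 90.8% of reads in SB210 and 74.9% in the Rdf1 knockout, 11.3% for Twi9 and 0.746% of distinct sequences for Twi12.

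Most 23 to 24 nt RNA began with U and many reads carried a 3' U beyond the part that matched the genome. The share of 23 to 24 nt reads beginning with U was 94.8% for Twi8, 90.1% for Twi10, 85.0% for Twi2, 80.9% for Twi7 and 40.6% for Twi9 (40.2 to 41.1). In total RNA it was 75.1% in CU522, 91.7% in SB210, 82.1% in the Rdf1 knockout, 80.3% in the Rdf2 knockout and 89.1% in the Rdn2 knockout. All of these are lower bounds, because sequences beginning with TTAG or later words are not listed. Reads that matched the genome only without a last U made up 65.3% of mapped reads for Twi7, 54.7% for Twi2, 49.2% for Twi10, 19.9% for Twi8 and 3.0% for Twi9. In total RNA they were 38.5% in CU522, 40.8% in SB210, 31.9% in the Rdf1 knockout, 36.2% in the Rdf2 knockout and 51.1% in the Rdn2 knockout, the library that lacks a nucleotidyltransferase.

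**Figure D2:**
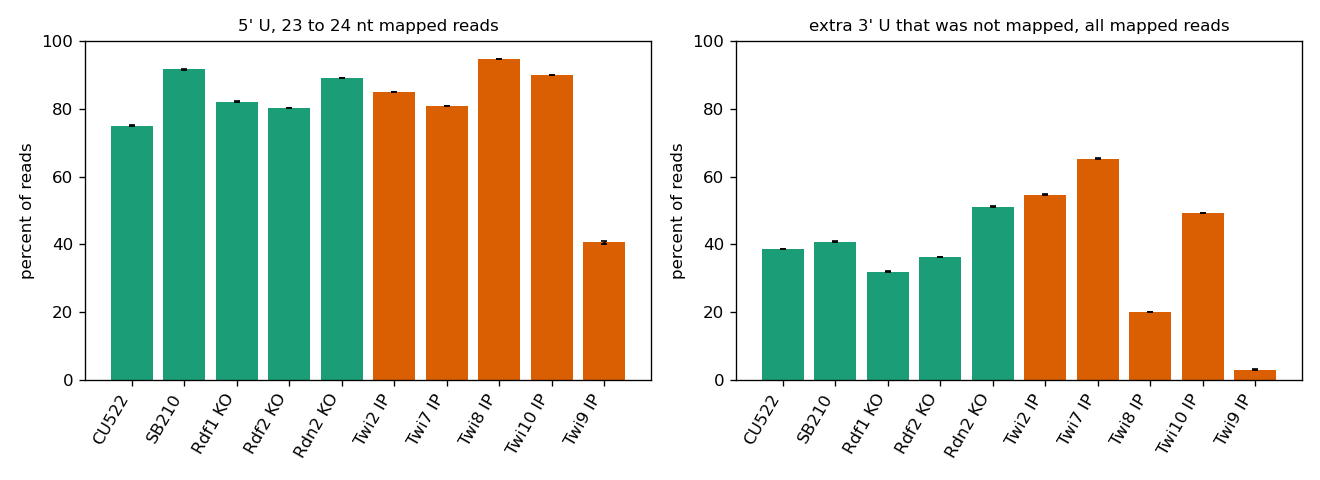
Percent of 23 to 24 nt mapped reads beginning with U (left) and percent of all mapped reads with an extra 3' U outside the genome match (right), for each library on the x axis; green bars are total RNA, orange bars are immunoprecipitates, and error bars are Wilson 95% intervals. The extra 3' U reaches 65.3% for Twi7 and 3.0% for Twi9.

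Non-mapped reads matched mapped RNA more often after trimming of the 3' end than of the 5' end when 2 or 3 bases were removed, with exceptions for Twi9, and for CU522 and Twi2 by distinct sequences. Removal of 2 bases from the 3' end turned 6.30% of the Rdf2 knockout's non-mapped reads, 2.49% of SB210's and 1.32% of the Rdn2 knockout's into a mapped sequence of the same library. Removal of 2 bases from the 5' end did so for 0.555%, 0.112% and 0.335% of them. Among the immunoprecipitates, removal from the 3' end gave 10% for Twi12, 4.59% for Twi9 and 1.35% for Twi2, against 3.18%, 5.60% and 0.570% from the 5' end, so Twi9 went the other way, though with 3 bases removed it gave 9.49% against 4.18%. Removal of 1 base from the 3' end gave 0 matches in all 11 libraries, because such reads are listed with the mapped sequences, against 0.0566% to 5.74% from the 5' end. Counted as distinct sequences, removal of 2 bases gave 1.05% against 0.493% in the Rdf2 knockout, 1.34% against 0.863% for Twi9 and 1.19% against 1.17% in CU522, and removal of 3 bases gave 0.947% against 0.951% in CU522 and 0.489% against 0.536% for Twi2. A read that begins with TTAG or a later word after 5' trimming cannot match, because such sequences are not listed. The 5' values are therefore lower bounds, and small differences between the ends are not interpreted.

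The wild types differed widely in which 23 to 24 nt sequences they held, which sets the background for every knockout. Of 4671 sequences tested between CU522 and SB210, 1806 were at least 4-fold higher in CU522 and 906 were lower. The most abundant sequence was the same in both, TATATCTGCGGAAAAAGCTATTT, which matched 1 genome position and held 3.07% of mapped reads in CU522 and 1.69% in SB210. TCTGTTTGATCTTCTGTGAGGGT, second in SB210 with 5200 reads, had 101 reads in CU522. At an equal depth of 100000 reads, CU522 held 41676 distinct sequences and SB210 held 20608. Over 12904 sequences the rank correlation between the wild types was 0.445, or 0.223 over the 3615 with at least 200 reads. Over the 12904 it was lower than that of SB210 with the Rdf1 knockout (0.694) or the Rdf2 knockout (0.691). It was higher than that of SB210 with the Rdn2 knockout (-0.15). Sequences are not independent replicates, so these correlations are descriptions only.

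Without Rdf1, more sequences were called lower than higher, but most of those beyond the difference between the wild types were higher. Of 1567 tested sequences, 464 were lower and 118 higher than in SB210, and of these 23 and 97 also exceeded the difference between the wild types. Sequences were admitted by their reads summed over the pair, which favours those abundant in the deeper library. That library was SB210, with 411355 mapped reads against 211744 in the Rdf1 knockout, so the excess of lower calls can reflect depth. The difference between the wild types uses the same SB210 library, so sequences admitted for being high there can be low in CU522 too and drop out. The excess of higher sequences beyond that difference can follow from this. Neither balance is therefore read as an effect of losing Rdf1. TACGGAGTGCCGGTTCGACCCCT, at 1 genome position, had 251 reads against 1 in SB210, a ratio of 488 (68.4 to 3475). Other leading sequences overlapped it or each other, since TCATTCCTACGGAGTGCCGGTTT shared TACGGAGTGCCGGTT with it and TCATTCCTACGGAGTGCCGGT with TCTCATTCCTACGGAGTGCCGGT. The latter had 121 reads against 1 (ratio 235, 32.8 to 1682). GGGAAGTCCCAGTGTCGACAACC, which matched 98 genome positions, had 127 reads against 1, but CU522 had 200 reads, so the wild types differed there as well. In this comparison 27.1% of all raised sequences matched over 10 positions against 4.53% of tested ones. TCATAAAATAGATCATAGCCAGT fell from 181 reads to 1, a 93.2-fold lower level (13.1 to 665), but had 9.80 RPM of mapped reads in CU522 against 440 RPM in SB210. TGTAAATAGGTTAATCGAATGTT fell from 81 reads to 2, with 197 RPM in SB210, 523 RPM in the Rdf2 knockout and 17.9 RPM in CU522, so the wild types differed in both. With CU522 as the control in place of SB210, 950 were lower and 280 higher, though CU522 was deeper still. With SB210 kept and sequences of 1 genome position, 78 were higher. Scaling to 23 to 24 nt reads raised the median log2 fold by 0.278.

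Without Rdf2, 758 of 3639 tested sequences were higher and 607 lower than in SB210, and 663 and 374 of these exceeded the difference between the wild types. Among the lowered ones were some of the most abundant RNAs of both wild types. TATATCTGCGGAAAAAGCTATTT had 109 reads in the Rdf2 knockout against 6948 in SB210, in a library with more mapped reads. TAAGAATAGCCTCTCTTTAAAAGC had 10 reads against 1637, a 556-fold lower level (299 to 1036), or a log2 fold of -6.80 in place of -9.12 when reads with the same first 18 bases were summed. TCAAAGAAGTGATATTCCCATTT had 1 read against 186 (632-fold lower, 88.6 to 4511), while the Rdf1 knockout had 538 RPM and the Rdn2 knockout 127 RPM, against 452 RPM in SB210. TGCAGTTAGATTTTATAATCCGT had 1 read against 233, but CU522 had none either, so the wild types differed there as well. Among raised sequences, TGATAATCGATTACTTTAGCATAT had 315 reads against 1 (ratio 92.7, 13.0 to 660), and GACACTTTGGCCGAGTGGTTAAG, at 15 genome positions, had 495 against 2 (ratio 72.8, 18.2 to 292). The wild types differed in both: the former had 11.5 RPM in CU522, against 225 RPM in the Rdf2 knockout and 2.43 RPM in SB210, and the latter 150 RPM, against 354 RPM and 4.86 RPM. TATGAGTGAGATTAATTTTTAAT, among the 5 most abundant of this library, had 10350 RPM against 2961 RPM in SB210, which is under the 4-fold rule, and 46.7 RPM in CU522. With CU522 as the control, 1712 were higher and 2164 lower, and with SB210 kept but reads summed over the first 18 bases 536 were higher and 634 lower, so no balance between rise and fall is given.

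The Rdn2 knockout had the largest share of changed sequences among the knockouts. Of 2582 tested, 1062 were lower and 703 higher, 776 and 542 of them beyond the difference between the wild types. TCTGAAGAATCATCCATTTGCTT had 1 read against 1069 in SB210, a 5271-fold lower level (742 to 37456), and 5980 reads in the Rdf2 knockout, but CU522 had 0 as well. TATGTAGTGCAACGGAATAATTT, at 16 genome positions, had 1 read against 934 (4606-fold lower, 648 to 32730), but CU522 had 101 RPM against 2271 RPM in SB210, so the wild types differed in it as well. TTAAGGTAGAGTTTTTTAAAGAT had 3 against 1435 (2359-fold lower, 760 to 7322), with 1237 RPM in CU522 and 3488 RPM in SB210. On the other side, overlapping sequences that each matched 1 genome position were higher together. TGATTAGAAGATAAGAGAAGCTTT had 6714 reads against 23 (ratio 59.2, 39.3 to 89.1), TATGATTAGAAGATAAGAGAAGCT had 5032 against 20 (ratio 51.0, 32.9 to 79.2), and both share TGATTAGAAGATAAGAGAAGCT, though CU522 had 414 and 160 RPM of the 2, against 55.9 and 48.6 RPM in SB210 and 3310 and 2481 RPM in this knockout. A further form, TATGATTAGAAGATAAGAGAAGT, held 7.14% of all mapped reads of this knockout. At 100000 reads this library held 57353 distinct sequences, against 20608 in SB210, 25456 in the Rdf1 knockout and 15699 in the Rdf2 knockout. With CU522 as the control, 2856 were lower and 602 higher.

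The sequences lower without Rdf1 were nearly all lower without Rdn2 as well, and the other pairs of knockouts overlapped in part. Of 1368 sequences tested in both the Rdf1 and Rdn2 knockouts, 446 were lower without Rdf1 and 1033 without Rdn2. Both had lower levels of 445, against 337 if the calls were independent and 0 in simulations without change, which hold counting error only. For the Rdf1 and Rdf2 knockouts it was 270 of 1401, against 195, and for the Rdf2 and Rdn2 knockouts 475 of 1365, against 445. The covariance of the log2 folds was 4.84, 1.83 and 0.556 for these pairs, and 0.0334, 0.0327 and 0.0934 in the simulations, while Pearson's r was 0.693, 0.318 and 0.0469, against 0.537, 0.509 and 0.814 in the simulations, so it was below the simulated value for the last 2 pairs. All 3 comparisons use the same SB210 library, so part of each excess over independent calls can come from that shared control, beyond the counting error that the simulations cover. Of the 464 sequences lower without Rdf1, only 23 were lower beyond the difference between the wild types, so most were low in CU522 as well. The overlap with the Rdn2 knockout therefore does not show a shared dependence on Rdf1 and Rdn2.

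Twi2 held RNA close in size to total RNA but shifted in sequence. Of 5569 sequences tested against CU522, 1016 were higher and 2161 lower. TCTCAGACAATCGAAGAGTATAT had 863 reads against 1, a ratio of 1024 (144 to 7279), and TGAAATCTCAGACAATCGAAGAT, which shares TCTCAGACAATCGAAGA with it, had 807 against 0, at least 319-fold higher. TACAACTTTGGAAGAATCAGACTT had 1117 reads against 0, at least 442-fold higher. The most abundant, TCCATCCTAAGAAATCTGTCAAT, held 3.82% of reads, with 55782 reads against 3354 in CU522. With SB210 as the control the balance turned, with 1516 higher and 987 lower.

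Twi7 was dominated by few sequences. TACAAATGTCTATTCTCAGGTGT, which matches 7 genome positions without its last U, held 24.4% of mapped reads (24.3 to 24.4), with 736974 reads against 742 in CU522. TAAGATGGTATATCTCAGCGTGT followed with 6.15% and AGATGGTATATCTCAGCGTGCATT with 4.66%, both at 2 positions. AAATAAGATGGTATATCTCAGCGT, which shares AGATGGTATATCTCAGCGT with the latter, had 6492 reads against 2 (ratio 1861, 465 to 7443). Of the 23 to 24 nt reads, 49.9% matched 2 to 10 positions, against 9.05% in CU522. Of 4678 tested sequences 560 were higher and 3255 lower, and 347 were higher among those with 1 position. The 10 most abundant sequences took 44.9% of reads, and scaling without them raised the median log2 fold by 0.718. With SB210 as the control 487 were higher and 1187 lower.

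Twi8 held a different leading RNA. TGATTAGAAGATAAGAGAAGCTT, at 1 genome position, made up 9.65% of its mapped reads (9.60 to 9.69), with 188206 reads against 1815 in CU522. TGCACACTGAGCAAATTTCACCA had 10809 reads against 22 (ratio 437, 288 to 664), or a log2 fold of 5.86 in place of 8.77 when reads with the same first 18 bases were summed, and its 22 nt form TGCACACTGAGCAAATTTCACC had 24699 reads. TGAGGGACTGCTTAAGAGTTTTT had 1032 reads against 1 (ratio 918, 129 to 6520). Of 4551 tested sequences 689 were higher and 3252 lower, and 97.2% of the raised ones began with U. Scaling to 23 to 24 nt reads raised the median log2 fold by 0.421 and left 726 higher, and with SB210 as the control 704 were higher and 1127 lower.

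Twi9 held longer RNA than the other Twi proteins with mapped counts. Of its 23 to 24 nt reads 46.5% matched 1 genome position and 33.5% matched 2 to 10, against 87.8% and 9.05% in CU522. Its most abundant sequence, GCACCGATGGTTTAGTGGTAGAATAGAGCG, had 30 nt, matched 29 genome positions and held 8.48% of reads (8.39 to 8.57). Within the 23 to 24 nt class, AGCAGGGTGGCGAAGTGGAATCGC, at 20 positions, had 2573 reads against 5 in CU522 (ratio 2430, 1010 to 5842), or a log2 fold of 7.03 in place of 11.25 when reads with the same first 18 bases were summed. AGCACCTGAGAATAGACATTTGT was the most abundant of that class with 8622 reads, and ATGCACGCTGAGATATACCATCT had 1276 against 13 (ratio 463, 268 to 800). Of 3654 tested sequences 46 were higher and 3071 lower, a share of 1.48% higher among those changed. The split depended on the scaling, because the class was small in Twi9: scaled to 23 to 24 nt reads, 133 were higher and 333 lower (28.5% higher), with a shift of the median log2 fold by 3.0. With SB210 as the control 37 were higher and 1127 lower.

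Twi10 shared its leading sequences with Twi2 and Twi7 and spread over more distinct ones. TACAAATGTCTATTCTCAGGTGT was first with 0.921% of its mapped reads, and TGAGAGCGATTCATTAATAAGCT, at 6 genome positions, second with 0.810%. TGAGAGCGATTCATTAATAAGCCT had 1610 reads against 11 in CU522 (ratio 211, 116 to 381). At 100000 reads Twi10 held 83125 distinct sequences, Twi8 64454, Twi2 38659, Twi7 34441 and Twi9 17925. Of 3910 tested sequences 126 were higher and 3121 lower. With SB210 as the control 218 were higher and 1118 lower, and with sequences of 1 position 76 were.

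Twi7 and Twi10 held the most similar RNA among the Twi proteins, with a rank correlation of 0.722 over 12904 sequences. It was 0.617 for Twi2 and Twi7, 0.590 for Twi7 and Twi8, 0.589 for Twi8 and Twi10 and 0.508 for Twi2 and Twi10, but 0.305 for Twi2 and Twi8, and between 0.152 and 0.217 for Twi9 with the other 4. Total RNA without Rdn2 resembled the immunoprecipitates more than SB210, with correlations of 0.637 with Twi7, 0.579 with Twi10 and -0.15 with SB210. Total RNA without Rdf2 had correlations of -0.55 with Twi7, -0.48 with Twi8, -0.48 with Twi10, -0.36 with Twi2 and 0.0750 with Twi9, and SB210 itself had -0.33, -0.34, -0.21, -0.0217 and 0.174. Sequences were chosen by their reads summed over the libraries, which can lower such correlations, and no value for unchanged libraries was computed.

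Sequences that changed in a knockout were next looked up in the immunoprecipitates. Those lower without Rdf2 lay above random lists matched on abundance for 4 of the 5 proteins: the median log2 fold was 1.10 with Twi2 (random lists -0.52 to 0.27), -2.76 with Twi7 (-4.46 to -3.10), -3.29 with Twi9 (-3.83 to -3.48) and -2.44 with Twi10 (-4.59 to -3.92). Of the 607, 348 had enough reads with Twi2 or CU522, and 428 were at least 4-fold lower in CU522 than in SB210, which can raise folds against CU522. For these 428, of which 169 were measured with Twi2, medians lay above random lists with Twi2 (1.41), Twi7 (-2.78) and Twi10 (-2.68). The median lay within them with Twi9 (-2.72) and below them with Twi8 (-5.05, against -4.87 to -4.29). Those higher without Rdf2 had a median of -3.31 with Twi2 over 185 sequences, against -1.43 to 0.08, and lay below all random lists for Twi7, Twi8 and Twi10 as well. Those higher without Rdn2 had a median of 1.85 with Twi2 over 412 sequences, -0.20 with Twi7, -1.64 with Twi8 and -0.56 with Twi10, each above all 10000 random lists. Those lower without Rdn2 lay below all random lists for Twi7 (-5.54), Twi8 (-5.84) and Twi10 (-4.78). Of the 464 lower without Rdf1, 105 had enough reads with Twi2 or CU522, and their median with Twi2 was 0.78, against -1.72 to 0.30. With Twi8 the median of this set was -5.35, against -5.03 to -4.26. Only 23 of the 464 were lower beyond the difference between the wild types. A sequence low in CU522 has enough reads over the pair only if it is high with Twi2. This favours positive folds among the 105, and among the 169 above, so no association with Twi2 is concluded from either. Of the 703 sequences higher without Rdn2, 435 had enough reads with Twi7 or CU522, 325 with Twi8 or CU522 and 332 with Twi10 or CU522. Members low in CU522 could enter only if high in the immunoprecipitate, as above. No association with a Twi protein is therefore concluded from the 703 either. Those higher without Rdf1 lay above random lists for Twi7 (-1.76, -4.31 to -2.39), Twi8 (-3.24, -5.71 to -4.01) and Twi10 (-2.14, -5.24 to -3.77). Random lists share the abundance but not other traits of the sets, and the knockouts and the immunoprecipitates have different wild-type controls. Many folds are bounds set by the floor of 3 counts. Of all tested sequences called lower, 2233 of 3071 had 0 reads with Twi9, 2045 of 3252 with Twi8, 1507 of 3121 with Twi10 and 1161 of 3255 with Twi7. With Twi2 it was 327 of 2161. Low medians can therefore reflect abundance in CU522 and depth.

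**Figure D3:**
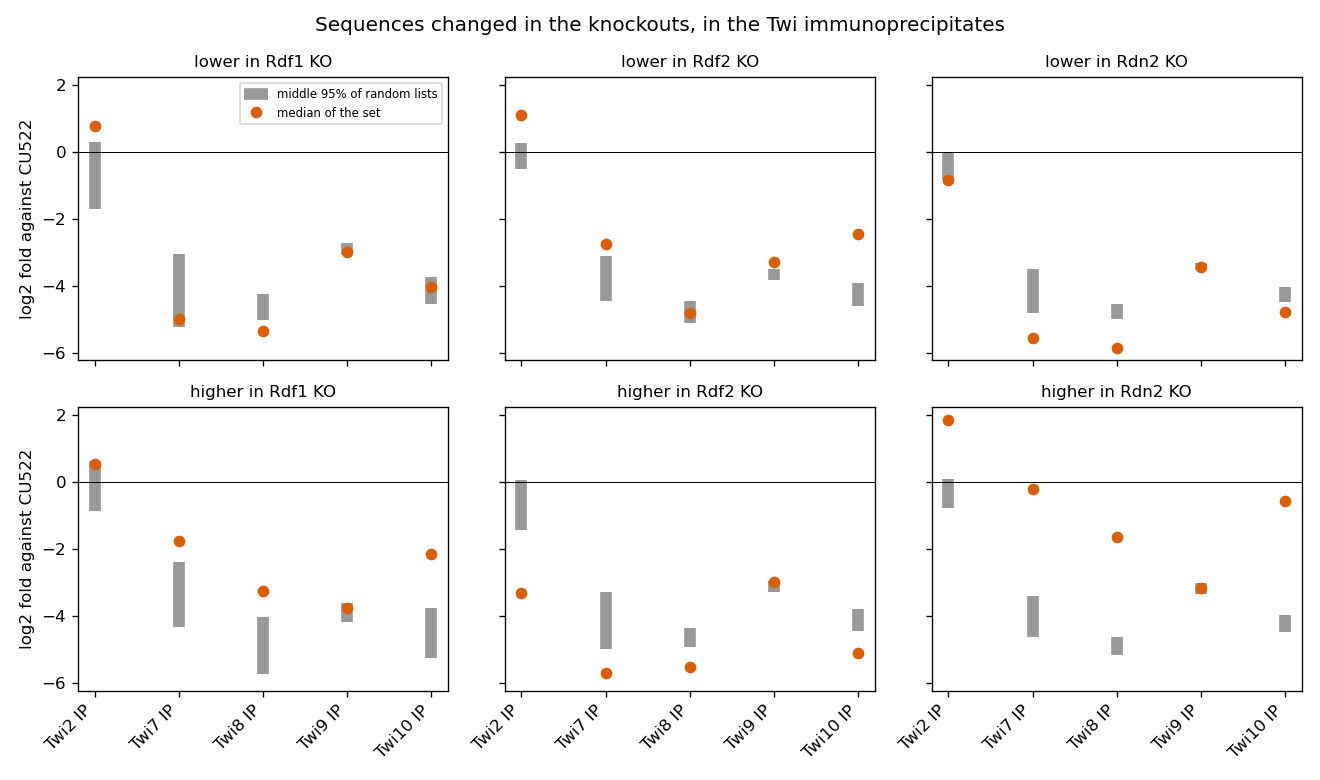
Median log2 fold against CU522 (y axis) in each immunoprecipitate (x axis) of the sequences lower (top) or higher (bottom) in each knockout than in SB210; points are set medians and grey bars the middle 95% of 10000 random lists matched on abundance. The set lower without Rdf2 has a median of 1.10 with Twi2 and -2.44 with Twi10, both above the random lists, and the set higher without Rdf2 -3.31.

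Reads with the tRNA pattern were common with Twi9 and among the non-mapped reads of Twi12 and more frequent in the Rdf1 and Rdf2 knockouts than in SB210. They made up 46.4% of the mapped reads of Twi9 (46.2 to 46.6), 15.7 times the 2.96% of CU522, and 50.4% of the non-mapped reads of Twi12, but 0.243% of its distinct mapped sequences, against 0.156% with the pattern at base 6. The difference between Twi9 and CU522 depended on size. It was 61.4% against 1.34% of mapped reads at 25 to 36 nt, 15.7% against 2.29% at 23 to 24 nt and 8.96% against 9.68% at 18 to 22 nt. Reads with the pattern made up 4.75% for Twi7, where 79.5% of them had 25 to 36 nt, and 4.52% for Twi2, 0.777% for Twi8 and 0.729% for Twi10, though 2.38% of the non-mapped reads of Twi10, against 0.726% in CU522. The pattern also matched a family of RNAs at 1 genome position that begin with TACTACATAGCAAAATCG, led by TACTACATAGCAAAATCGAAGGT. This family held 88.8% of the matching mapped reads of Twi2, 78% of those of the Rdn2 knockout, 36.1% of those of Twi10, 29.3% of those of CU522 and 25.8% of those of SB210. Without it the share was 0.528% for Twi2 against 2.11% in CU522, so Twi2 lay below CU522 and not above it. The share was 7.38% in the Rdf1 knockout, 9.11% in the Rdf2 knockout and 2.45% in the Rdn2 knockout, against 2.80% in SB210. Without the family these were 6.13%, 9.08% and 0.548%, against 2.09%. GCACCGATGGTTTAGTGGTAGAA alone, at 29 genome positions, held 4.51% of the reads of the Rdf2 knockout and 0.857% of those of SB210. The ratio to SB210 was 2.64 (2.58 to 2.70) without Rdf1 and 3.25 (3.19 to 3.32) without Rdf2. Over mapped and non-mapped reads together the log2 ratio for Rdf1 fell from 1.40 to 0.75. That for Rdn2 turned from -0.19 to 0.14 with the family and was -1.26 without it, so the family carried the turn.

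Reads of the telomeric G strand were more frequent without Rdf1 and with Twi10 and less frequent without Rdf2. The Rdf1 knockout had 1347 such reads, 2083 RPM of all listed reads, against 156 RPM in SB210, a ratio of 13.3 (11.2 to 15.9). The Rdf2 knockout had 30 reads, 8.53 RPM, a ratio of 0.0547 (0.0368 to 0.0812), and the Rdn2 knockout 115 RPM. Twi10 had 379 RPM against 77.9 RPM in CU522, a ratio of 4.87 (4.22 to 5.62), and Twi8 had 27 RPM. Few of these reads were of the usual size, with 11.7% at 23 to 24 nt in the Rdf1 knockout and 16.8% for Twi10. The C strand gave 11 reads in the Rdf1 knockout and 0 in SB210, and shuffled repeats gave 0 in both and 22 for Twi10. G-strand reads that begin with TTGGGG are not listed, because the lists stop at TTACAA. The G-strand values and ratios leave these out, and their number in each library is not known. With at least 18 consecutive bases the log2 ratio of the Rdn2 knockout went from -0.44 to -1.14 and that of Twi7 from -0.12 to -2.06.

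**Figure D4:**
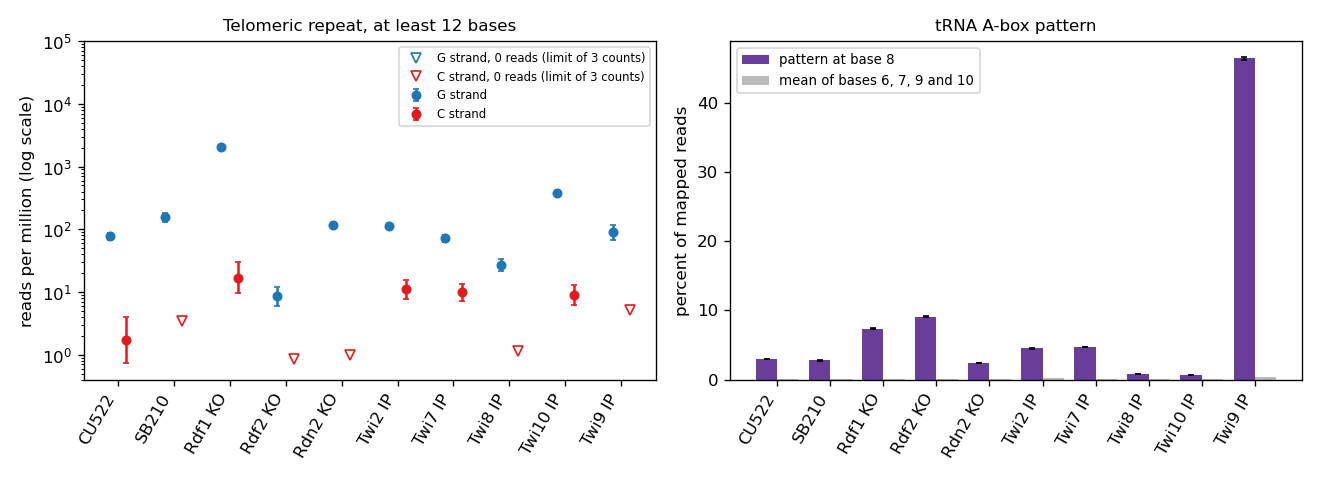
Telomeric reads (left, RPM of all listed reads on a log axis, G strand in blue and C strand in red, open triangles for the limit a count of 0 allows) and reads with the tRNA pattern (right, percent of mapped reads, purple at base 8 and grey for the mean of neighbouring starts), by library; error bars are 95% intervals. The G strand reaches 2083 RPM in the Rdf1 knockout, and the tRNA pattern 46.4% for Twi9; the value of 4.52% for Twi2 is 0.528% without the family of TACTACATAGCAAAATCG.

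Opposite-strand partners with an overlap of 22 bases, the offset of paired Dicer products of 24 nt with 2-base 3' overhangs, stood out in wild-type RNA and not in most immunoprecipitates. Of distinct 23 to 24 nt sequences with 1 genome position and no extra 3' base (14347 in SB210 and 163506 in CU522), 2.73% in SB210 and 2.86% in CU522 had such a partner, 1.85 times (1.64 to 2.08) and 1.23 times (1.19 to 1.27) the mean of overlaps of 19, 20, 21 and 23 bases. The ratio was 1.62 in the Rdf1 knockout, 1.40 in the Rdf2 knockout and 0.950 in the Rdn2 knockout. It was 1.92 for Twi9, 1.06 for Twi10, 0.983 for Twi2, 0.930 for Twi7 and 0.759 for Twi8. Reversed sequences gave 0 partners at 22 bases in every library. Drawn down to 10000 distinct sequences the log2 ratio was 0.76 in CU522 in place of 0.30 and -0.06 for Twi2 in place of -0.02, so ratios of libraries with different numbers of sequences are not on 1 scale.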

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

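The tests on long reads with the tRNA pattern and on the first base were chosen after the result was seen, and the test of the first 18 bases was set before its value was known. The values of this part come from non-mapped reads, which the comparisons of mapped RNA do not use, and each stands above the level in the CU522 total library, the control.

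Long non-mapped reads ending in a run of T stood out with Twi10. Reads of at least 30 nt that end in 6 or more T made up 21.1% of the non-mapped reads of Twi10 (21.1 to 21.2), against 0.00197% in CU522. They made up 0.384% for Twi9, 0.0487% for Twi12 and 0.0315% for Twi7. In Twi10 the part before the run had a median of 24 nt, and 92.1% of these reads had 22 to 25 bases before it. Of the long Twi10 reads with the tRNA pattern 1.35% ended so, against 30.2% of all its long reads. This does not decide whether T runs are read at the end of any long insert. Reads had at most 36 nt, so a run of 6 T shows only after a shorter insert, and insert lengths were not matched. Whether T was added to the genome-mapped RNAs of this library is not decided either. The first 18 bases of 13.7% of the reads ending in T runs began a mapped sequence, against 44.2% of mapped reads tested against each other. That 44.2% includes copies of the same sequence, which PCR can make, so it can be too high a background. The first base argues against cores of the same kind as the mapped RNAs, since 39.9% of the reads ending in T runs began with T, against 90.1% of mapped 23 to 24 nt reads. RNA tailed in the cell, from places the authors' genome did not hold, may still account for the T runs, as may a step of this library's preparation, and neither was tested.

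Reads with the tRNA pattern were common among non-mapped reads of Twi12, at 50.4% (50.3 to 50.5), and of Twi9, at 35.0%, and reached 3.77% for Twi7 and 2.38% for Twi10, against 0.726% in CU522. In Twi12, 2.40% of non-mapped reads became a mapped sequence after removal of a final CCA, the ending added to mature tRNA, against 0.0521% in CU522. Of these Twi12 reads 98.1% had 18 to 22 nt, and removal of a final CAC gave 0.0310% and of a final ACC, which has the same bases, 0.791%, and these values do not separate CCA added to tRNA from other causes of such ends. No biological explanation was tested for these reads.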

How the results depend on the processing

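No paired analysis was possible because each group has 1 library. The alternatives without an extra 3' base, without the tRNA pattern, over all reads for the tRNA pattern, without the family of TACTACATAGCAAAATCG and with over 1 genome position for the same, with sums over the first 18 bases, with every count under the floor raised, without the 10 most abundant sequences, with 10000 drawn sequences and with the other wild type for counts of sequences were chosen after seeing the data; the others were planned. Where no reason is given, the cause was not tested. Log2 ratios of the 23 to 24 nt share kept their sign for Rdf1, Rdf2, Rdn2, Twi8, Twi9 and Twi10 under the alternatives run. By distinct sequences they were -0.22 for Rdf1, -0.12 for Rdf2, 0.10 for Rdn2, -0.50 for Twi8, -2.34 for Twi9 and -0.0897 for Twi10, and turned to -0.0266 for Twi2 and 0.0116 for Twi7. Against the other wild type they were -0.27 for Rdf1, -0.0368 for Rdf2, 0.0605 for Rdn2, 0.0519 for Twi2, -0.0456 for Twi7, -0.43 for Twi8 and -0.0889 for Twi10. Without reads with an extra 3' base they were -0.44 for Rdf1, -0.0583 for Rdf2, 0.0703 for Rdn2, 0.0961 for Twi2, -0.34 for Twi7, -0.50 for Twi8, -3.17 for Twi9 and -0.14 for Twi10. Without reads with the tRNA pattern they were -0.25 for Rdf1, -0.0195 for Rdf2, 0.0428 for Rdn2, 0.0491 for Twi2, -0.43 for Twi8, -2.36 for Twi9 and -0.0895 for Twi10, and turned to 0.00980 for Twi7. A minimum of 200 reads tested fewer sequences and left fewer called: higher and lower were 21 and 135 for Rdf1, 218 and 148 for Rdf2, 161 and 248 for Rdn2, 262 and 481 for Twi2, 131 and 770 for Twi7, 88 and 742 for Twi8, 9 and 814 for Twi9, and 23 and 715 for Twi10. Against CU522 the knockouts had 280 higher and 950 lower for Rdf1, 1712 and 2164 for Rdf2, and 2856 lower for Rdn2. Against SB210 the immunoprecipitates had 987 lower for Twi2, 1187 for Twi7, 1127 for Twi8, 1127 for Twi9 and 1118 for Twi10, and 218 higher for Twi10. With sequences of 1 genome position, which admits fewer, 78 were higher for Rdf1, 347 for Twi7, 15 for Twi9 and 76 for Twi10. Scaled to 23 to 24 nt reads, Twi9 had 133 higher and 333 lower, because the class is small in Twi9. The other counts of sequences stayed within 1.5 times: 16 each with sums over the first 18 bases, raised counts and scaling without the 10 most abundant, 14 with scaling to 23 to 24 nt reads and 12 with 1 position, though the balance for Rdf2 turned, to 536 higher and 634 lower, with sums over the first 18 bases. Without the 10 most abundant the median log2 fold rose by 0.718 for Twi7, 0.293 for Twi9, 0.157 for Rdn2 and 0.129 for Twi8. With at least 18 telomeric bases the log2 ratio was -1.14 for Rdn2, 0.16 for Twi2 and -2.06 for Twi7, and 5 others stayed within their intervals. Over mapped and non-mapped reads the tRNA pattern gave log2 ratios of 0.75 for Rdf1, 1.32 for Rdf2, 0.31 for Twi2, 1.13 for Twi7, -1.63 for Twi8, 4.36 for Twi9 and -0.28 for Twi10, and turned to 0.14 for Rdn2. Without the family of TACTACATAGCAAAATCG, RNAs at 1 genome position that match the pattern, mapped reads gave 1.55 for Rdf1, 2.12 for Rdf2, -1.93 for Rdn2, 1.08 for Twi7, -1.51 for Twi8, 4.46 for Twi9 and -2.18 for Twi10, and turned to -2.0 for Twi2. Over all reads without it they were 0.85 for Rdf1, 1.66 for Rdf2, -1.26 for Rdn2, 1.48 for Twi7, -1.27 for Twi8 and 4.78 for Twi9, and turned to -1.68 for Twi2 and 0.00528 for Twi10. Sequences with over 1 genome position gave 1.55 for Rdf1, 2.15 for Rdf2, -2.21 for Rdn2, 1.08 for Twi7, -1.61 for Twi8, 4.36 for Twi9 and -2.36 for Twi10, and turned to -2.12 for Twi2. The turn for Twi2 comes from that family, which holds 88.8% of its matching mapped reads. Folds of single named sequences kept their direction, 50 within and 5 outside their intervals when scaled to 23 to 24 nt reads, and 44 and 11 when summed over the first 18 bases. Shares of 23 to 24 nt reads and of 5' U moved beyond their narrow counting intervals in all 10 libraries with a 22 to 25 nt window, with distinct sequences and with both files together. Matching of trimmed non-mapped reads moved for 22 values with distinct sequences and for 21 with a match to any library. Rank correlations with at least 200 reads moved for 9, among them the wild types (to 0.223), and held for 10. The log2 ratio of the overlap in CU522 went from 0.30 to 0.76, and 4 held. Not run for want of coordinates or annotation were 5 kb bins, phasing by reads and by unique sequences, strand bias of loci, matches within 5 nt of tRNA genes and a denominator without structural RNA; 10000 drawn sequences gave no overlap ratio for Twi7, Twi8, Twi10 or Rdn2, which then had too few partners, or for Twi9, which has 5161 sequences in all. Depth limits the Rdf1 knockout most, with 1567 sequences tested.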

Other observations

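The tests of the G-strand reads against tRNA fragments and the C strand, of association with Twi2, of the part of the set not lower in CU522, and of single cultures were chosen after the results were seen. The tests of 1 dominant sequence, of tRNA reads in the totals and of the wild-type difference were set before their values were known.

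The sequences of this paragraph were chosen after their values were seen. RNA from the strand opposite to the main RNAs of Twi7 was present with Twi9, with Twi8 and with Twi7 itself. The leading Twi7 RNA, TACAAATGTCTATTCTCAGGTG without its last base, had its full reverse complement from base 3 of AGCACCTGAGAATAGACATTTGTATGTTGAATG, a 33 nt sequence at 7 genome positions with 28737 reads in Twi7 itself. Shorter forms with the same start were abundant in Twi9, where AGCACCTGAGAATAGACATTTGTATGTTG had 7072 reads. Sequences that begin with AGCACCTGAGAATAGACA held 8.35% of the mapped reads of Twi9, 2.96% of those of Twi7 and 0.0566% of those of CU522. Another of the leading Twi9 sequences, ATGCACGCTGAGATATACCATCT, shares all of AGATGGTATATCTCAGCGTGCAT, on the opposite strand, with an abundant Twi7 RNA. Of the 200 most abundant Twi7 sequences, 45 had a partner on the opposite strand over at least 18 bases among the 200 most abundant of Twi9, and they held 75.2% of the reads of these 200. Twi8 in place of Twi9 gave 51 (74.2% of the reads), Twi7 itself 48 (49.8%), the Rdf1 knockout 27, Twi2 23, the Rdn2 knockout 21, Twi10 19, CU522 11, the Rdf2 knockout 7 and SB210 1, so the partners were not particular to Twi9. Reversed sequences gave 0 partners in each of these.

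Among the listed reads, which leave out those beginning with TTGGGG, telomeric G-strand reads were 13.3 times as frequent in the Rdf1 knockout as in SB210. Reads with the tRNA pattern rose less, with a log2 ratio over all reads of 0.75 (0.85 without the family of TACTACATAGCAAAATCG), against 3.74. This argues against a rise of equal size in all RNA fragments. It cannot exclude a general rise, because tRNA fragments need not rise as much as others. Fragments of double-stranded telomeric DNA are argued against by 11 C-strand reads against 1347 of the G strand, and amplification of a single molecule by the share of the most abundant sequence, 30.4% among 213 distinct ones. A difference between single cultures or libraries cannot be told apart from the loss of Rdf1, because there was 1 Rdf1 knockout library. Telomeric transcripts kept or made at higher levels without Rdf1 may therefore be offered only as a hypothesis, which counts of G-strand reads in another Rdf1 knockout library would test.

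The sequences lower without Rdf2 had a median log2 fold of 1.10 with Twi2, against an upper end of 0.27 in random lists. Reads taken up by tRNA fragments in the Rdf2 knockout are argued against, since leaving these reads out of the totals moved the median by 0.0969, from -5.34. The difference between the wild-type libraries goes with most of the set, with a median log2 fold of -4.05 in CU522 against SB210 and 428 of the 607 at least 4-fold lower there, and because CU522 is also the control of Twi2, an association with Twi2 cannot be told apart from it for these. The other 179, of which 11 were at least 4-fold higher in CU522, had a median of -4.88 in the Rdf2 knockout against CU522 (quartiles -6.54 and -3.09). They were chosen on these libraries, which forces a lower value than in CU522 but not its size. They therefore lay below both wild-type libraries, in 1 Rdf2 knockout library, and no verdict on the wild-type difference is drawn. Their median with Twi2 was 0.82 (upper end of random lists 0.71). They lay above random lists with Twi8 (-4.18, upper end -4.29), Twi9 (-3.59, -4.02) and Twi10 (-2.33, -3.84) as well, which does not single out Twi2. A difference between single cultures or libraries cannot be told apart from the loss of Rdf2, with 1 Rdf2 knockout library.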
